A study of Homo sapiens with 8 samples.

How the data were processed

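RNA was sequenced in 8 libraries from a human lymphoblastoid cell line (B cells that grow without limit after infection with Epstein-Barr virus). Per the labels, cells were grown in RPMI medium and treated with 5 µM hexavalent chromium for 24 h, and libraries were made from control cells, from cells at 24 h of exposure and from cells 3 and 7 days post treatment. The labels describe 2 biological replicates for each of the 4 groups. Per the labels' protocols, mRNA was selected with poly-T beads in 2 rounds, libraries were made with a PrepX RNA-Seq kit and 15 cycles of PCR, 12 libraries were combined in each mix, and paired reads of 150 bases were collected on an Illumina HiSeq instrument.

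The deposited values are whole-number read counts per gene symbol, with a separate table for each library and no pooling of replicates. Trim Galore, Bowtie2, SAMtools, DESeq2 1.8.1 and R 3.2.3, with the builds GRCh37 and hg19, are named in the submitters' processing notes. The counting tool, its strand setting and the annotation release are not given in the sources used here. Each table held 23710 gene symbols and 5 summary entries that name no gene, in the form that htseq-count writes. Those 5 entries took 42.6% to 57.5% of the reads in a table and were left out of library sizes and tests. Most were reads counted under no feature (36.5% to 51.5%). With the counting settings not given, such reads need not lie outside genes. No entry was a mitochondrially encoded gene, so the share of mitochondrial counts and the list of those genes could not be measured. Without a stated strand setting, reads of overlapping and antisense genes cannot be told apart, and genes with near-identical copies are called uncertain.

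From the counts, genes were kept with the default filter of edgeR 4.0.16 (filterByExpr, minimum count 10 and minimum total 15), which left 12536 genes. Library sizes were scaled with TMM factors, and the quasi-likelihood test of edgeR (glmQLFit, glmQLFTest) was fitted to all 8 libraries with a coefficient per group and no covariate, so that the groups shared a single estimate of the spread. The common biological coefficient of variation was 0.276, with 4 residual and 4.09 prior degrees of freedom. Calls were made at an adjusted p under 0.05 after Benjamini-Hochberg adjustment over the genes tested in each of 6 comparisons, and in a joint test of the 3 exposed groups against control. CPM stands for read counts scaled by TMM-adjusted library size. Log2 CPM used a prior count of 2. Standard errors of fold changes were derived from the F statistic. Values per gene are CPM, as mean ± SD of 2 libraries.

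Before the data were examined, 37 gene lists were fixed for this cell type and treatment, and 32 had at least 5 tested members. Symbols were matched also through the synonyms of the RefSeq table for GRCh38, from which no position is used. Lists were tested with camera (limma 3.58.1), a competitive test with a preset correlation of 0.01 between genes, with adjustment over the 96 tests of the 3 comparisons with control. The same test for the 3 comparisons between exposed groups was not among those fixed in advance and was adjusted separately. Camera with an estimated correlation and fry, which asks whether a list moves in 1 direction on balance, were run as alternatives.

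Genes were named by a rule fixed in advance: genes past the threshold, with at least 2 CPM in the higher group, both libraries of a group on the same side of both libraries of the other, and a symbol that is not a clone identifier. Fewer than 10 genes qualified in each comparison, so the rule adds genes by smallest unadjusted p up to 10; the level, separation and symbol criteria were kept for these. For each list, up to 4 members with the smallest p are candidates for naming. Genes named outside this rule are stated to be so.

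The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0 on all 23710 genes with its own filtering, limma-voom, no filter and a stricter filter on counts (at least 50 in at least 2 libraries), a fit of only the 2 groups compared, robust empirical Bayes, the replicate number as a block, and each library left out in turn. DESeq2 on the genes that edgeR used, a block with crossed numbers, a fit without replicate 1 at 3 and 7 days, and a contrast of the 2 later groups with the 2 earlier groups were chosen after seeing the data.

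The procedure was tested on simulated data drawn for the 12536 genes from the real means, dispersions and library sizes, with 200 genes changed. For 24 h against control, 2% of genes changed 2-fold, 82% changed 4-fold, 94% changed 8-fold and 96% changed 16-fold were recovered in the right direction, with 11 false calls. For 3 days against control these shares were 8%, 74%, 90% and 96% with 9 false calls, and for 7 days 8%, 60%, 88% and 92% with 9 false calls. A simulated shift of the NF-kB list by -0.5 on the log2 scale was called by camera in each of the 3 comparisons with control, and in none of them with an estimated correlation (adjusted p from 0.218 to 0.927), so the estimated correlation had little power for a shift of that size. Of the other 95 list tests in each simulation, 0, 0 and 1 were called. Genes and libraries were drawn independently in these simulations, whereas the real libraries form close pairs across groups. The shares recovered may therefore not hold for the real data. The simulations therefore cannot show how often camera, with its preset correlation, calls lists whose members vary together without a group effect. In the real data the estimated correlation was 0.589 for DNA replication, 0.353 for the ATF4 list and 0.033 for B cell activation, against the preset 0.01. Loss of a call with the estimated correlation therefore need not reflect low power alone. The p values with the preset correlation may be too small for such lists.

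Total counts in genes ranged from 9478459 to 11110830 per library. Total count, the share of reads under no feature, the share of reads aligned to more than 1 place, the number of genes with a count and the share in the 20 highest genes were compared over the 4 groups. The test was an exact permutation test over every split of 8 libraries into 4 pairs, for which the smallest possible p is 0.00952. Fold change correlations were set beside unchanged groups simulated 50 times against the same controls. A first simulation pooled the spread over groups; after its values were seen, a second was made with the spread of each group, and both are given. Both draw libraries independently, so neither carries a likeness of libraries beyond the shared controls. Correlations of fold changes from single libraries, with no library in common, were also added after seeing the data. Smooth trends of expression differences on gene span, transcript length, GC content and mean expression were fitted with mgcv 1.9.3, using GENCODE 29 lengths and sequences, which 96.8% of the tested genes had. Fold changes for these trends were differences of mean log2 CPM rather than edgeR estimates. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.

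The labels do not say that a replicate number marks a shared culture or day. The replicate differences of the groups did not all correlate positively, so the numbers were not taken to pair the samples.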

Results

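Gene expression was measured by RNA sequencing in a human lymphoblastoid cell line before exposure to 5 µM hexavalent chromium, at 24 h of exposure, and 3 and 7 days post treatment, with 2 libraries in each of the 4 groups. The sample labels count the days as post treatment, whereas the series describes time points after the onset of exposure, so the origin of the day count is open. The total gene counts were 10884838 and 9478459 in the control libraries and 9587004 and 10434228 at 24 h. They were 10403981 and 11110830 at 3 days, and 9940751 and 9920202 at 7 days. Between 14963 and 15828 genes had at least 1 count. The 20 highest genes took 12.5% of counts in replicate 1 at 3 days and in replicate 1 at 7 days, and from 8.88% to 9.65% in the other libraries. None of 5 library measures differed over the groups in an exact permutation test (p from 0.229 to 0.61, adjusted p from 0.444 to 0.61).

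B cell identity genes were abundant, with a median over 25 genes of 81.1 to 114 CPM (read counts scaled to library size) per library. Markers of other cells were close to absent: 1 of 15 T and NK cell markers, 2 of 14 myeloid markers, 0 of 15 stromal or epithelial markers and 0 of 9 erythroid markers reached 10 CPM in any library. Each library was closest to a library of another group. Control replicate 1 was closest to 24 h replicate 2, control replicate 2 to 24 h replicate 1, and the 3 day and 7 day libraries of the same number to each other. The chi-square per degree of freedom of these 4 pairs was 4.33 to 6.17, against 22.6 for the control replicates, 25.9 at 24 h, 88.4 at 3 days and 73.1 at 7 days.

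**Figure D1:**
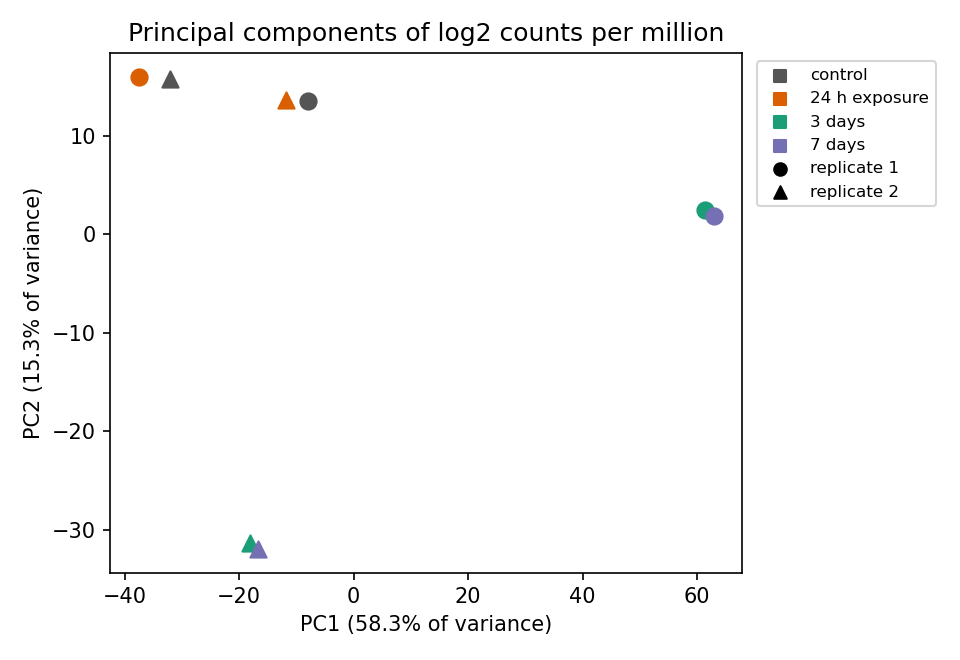
Principal components of log2 CPM over 12536 genes, with PC1 (58.3% of variance) on the x axis and PC2 (15.3%) on the y axis; each point is a library, colour gives the group and shape the replicate number. Replicate 1 at 3 days (61.4) and at 7 days (62.9) lie apart on PC1, and replicate 2 at 3 days (-31.4) and at 7 days (-31.9) on PC2.

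The comparison of 24 h exposure with control asks what differed at 24 h of chromium exposure. Control cells were sampled before exposure, and no unexposed cells at 24 h were analysed here. Exposure and time in culture therefore cannot be told apart in it. Replication-dependent histone genes, which package newly made DNA, fell as a list: all 10 tested members were lower, with a median log2 fold change of -0.39 (camera, adjusted p = 1.2e-06; adjusted p = 0.354 with an estimated correlation). HIST2H2BE stood at 4.45 ± 0.38 CPM against 6.83 ± 0.53 in control, and HIST1H2BC at 1.02 ± 0.26 against 2.22 ± 0.77 (SD, n = 2). These genes share reads with near-identical copies and most lack a poly-A tail, so their levels in poly-A selected RNA are uncertain. Aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, also fell as a list, with 17 of 20 members lower and a median of -0.09 (camera, adjusted p = 0.0496; adjusted p = 0.789 with an estimated correlation). That call held in 1 of 8 fits with a library left out, where its adjusted p ranged from 0.045 to 0.402.

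The other 30 lists did not pass at 24 h (adjusted p from 0.0709 to 0.967). This count rested on single libraries: in place of 2 lists, 15 were called without 24 h replicate 1, 9 without control replicate 1, control replicate 2 or 24 h replicate 2, and 1 without 3 day replicate 1 or either 7 day library. Among lists fixed for the response to chromium, p53 targets had a median log2 fold change of 0.03 over 39 genes, NRF2-driven antioxidant genes -0.11 over 25, and metallothionein and metal-responsive genes 0.01 over 6. Only MT1E, MT1X and MT2A among these 6 are metallothioneins, and the other metallothioneins on the list fell below the count filter. That median therefore says little about metallothioneins. MT2A, a metallothionein, stood at 3.75 ± 0.48 CPM against 3.38 ± 0.43 in control. No list had a member past the threshold, adjusted over the list alone (0 genes) or over all genes (0).

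No single gene passed at 24 h: edgeR called 0 of 12536 genes, DESeq2 0 and limma-voom 0, and 22 genes had an unadjusted p under 0.05 in edgeR, against 627 expected by chance. The spread was shared over groups whose median biological coefficients of variation were 0.17 in control, 0.19 at 24 h, 0.33 at 3 days and 0.32 at 7 days; a fit of control and 24 h alone gave 104 such genes and 0 calls, and leaving out 24 h replicate 2 gave 35. The smallest unadjusted p values included TMEM126A (46.5 ± 7.69 CPM against 28.4 ± 4.02 in control, log2 fold change 0.71 ± 0.26 SE) and TMEM126B (33.9 ± 1.73 against 23.0 ± 0.33, 0.56 ± 0.21), which encode mitochondrial membrane proteins. FAHD2A (-0.69 ± 0.26) and FAHD2B (-0.65 ± 0.24) are near-identical genes and therefore uncertain. TAS2R4 (2.07 ± 0.68), C15orf61 (1.49 ± 0.49), FAM161B (-1.49 ± 0.50) and KCTD17 (-1.05 ± 0.41) completed the larger values, each with an adjusted p of 1. Both 24 h libraries lay on the same side of both control libraries for 23.9% of genes, where chance gives 33.3%. Control and 24 h libraries of different numbers resembled each other (correlation of replicate differences -0.60), and the unpaired fits count the gap between replicates as noise. Their 0 calls and the low share of separated genes therefore do not show that 24 h and control were alike.

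At 3 days post treatment, compared with control, the genes with the smallest p were mostly lower. ITGA1, the alpha-1 integrin subunit, stood at 21.7 ± 1.35 CPM against 73.8 ± 4.89 in control (log2 fold change -1.77 ± 0.21 SE, adjusted p = 0.359; n = 2 per group, SD beside means). VCAM1, a cell adhesion molecule, stood at 0.95 ± 0.18 against 6.23 ± 1.13 (-2.70 ± 0.42). RASSF4 stood at 14.2 ± 1.42 against 38.9 ± 3.82 (-1.46 ± 0.22), and the chemokine gene CCL22 at 225 ± 41.7 against 629.5 ± 135 (-1.49 ± 0.26). LTA, which encodes lymphotoxin alpha, was at 96.9 ± 13.4 against 411 ± 171 (-2.09 ± 0.40). MGST3, a microsomal glutathione transferase, was higher, at 25.9 ± 0.15 against 10.9 ± 1.56 (1.24 ± 0.24). Both 3 day libraries lay on the same side of both control libraries for 33.9% of genes, where chance gives 33.3%. edgeR called 0 of 12536 genes. Against 627 expected by chance, 663 had an unadjusted p under 0.05 (270 higher and 393 lower). That number was 410 without control replicate 1, 188 without control replicate 2, 337 without 3 day replicate 1 and 1898 without 3 day replicate 2. limma-voom called 0. DESeq2, run without the count filter, called 0 higher and 9 lower, among them ITGA1, VCAM1, RASSF4, CCL22, LTA and NTRK2, and on the 12536 genes that edgeR used, an alternative chosen after seeing the data, it called 1 higher and 12 lower.

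NF-kB target genes fell as a list at 3 days, with 26 of 27 members lower and a median log2 fold change of -0.60 (camera, adjusted p = 3.0e-15; adjusted p = 0.377 with an estimated correlation). For 20 of the 27, both libraries lay below both controls, where chance gives 16.7% of genes. Adjusted over the list alone, 4 members were lower, and 0 over all genes. NFKB2, which encodes the p100 and p52 subunits, stood at 76.1 ± 3.49 CPM against 149 ± 2.86, and TRAF1, a signalling adaptor, at 95.95 ± 9.67 against 181 ± 19.8. Activation genes of B cells, a list that shares CCL22, TRAF1, CD83, ICAM1 and EBI3 with the former, fell with 19 of 22 members lower and a median of -0.35 (adjusted p = 8.7e-07; adjusted p = 0.354 with an estimated correlation), and 4 passed adjusted over the list alone. The costimulatory gene CD80 stood at 110 ± 6.14 against 205 ± 18.1 and the interleukin-2 receptor gene IL2RA at 11.3 ± 0.62 against 23.5 ± 0.87. Interferon-stimulated genes fell too, with 26 of 30 lower and a median of -0.60 (camera, adjusted p = 1.5e-09, or 0.789 with an estimated correlation). Adjusted over the list alone, 0 of them passed, and GBP1 stood at 86.3 ± 3.07 against 153 ± 2.84. The fall was larger in replicate 1: the interferon median was -0.80 there and -0.41 in replicate 2, against -0.21 and 0.21 in the control libraries.

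Hypoxia and glycolysis genes rose as a list at 3 days, with 31 of 32 members higher and a median of 0.62 (adjusted p = 2.0e-11; adjusted p = 0.637 with an estimated correlation). BNIP3, a mitophagy receptor, stood at 253 ± 44.6 CPM against 125 ± 23.4. G2/M and mitosis genes rose, 31 of 32 higher with a median of 0.35 (adjusted p = 5.6e-08; adjusted p = 0.789 with an estimated correlation), and CDK1, the mitotic kinase, stood at 336 ± 38.7 against 227 ± 13.4. DNA replication genes rose, 33 of 36 higher with a median of 0.48 (camera, adjusted p = 5.6e-08, or 0.968 with an estimated correlation). The control libraries themselves lay apart for this list, at 0.24 and -0.24, against 0.50 and 0.34 in the 3 day replicates. PRIM1, a primase subunit, stood at 37.6 ± 3.81 against 25.98 ± 3.01. Genes of the ATF4 amino acid response rose, 23 of 29 higher with a median of 0.16 (adjusted p = 0.0172; adjusted p = 0.968 with an estimated correlation), a call that was lost without control replicate 1 or either 3 day library (highest adjusted p 0.668). Its median was 0.10 in replicate 1, inside the control libraries (-0.25 and 0.25), and 0.31 in replicate 2. With a trend on gene length and GC content removed, the ATF4 median went from 0.17 to 0.04, inside matched random lists (-0.16 to 0.12). Adjusted over the list alone, 0 members of these 4 lists passed. The other 21 lists did not pass at 3 days (adjusted p from 0.0789 to 0.982). Among them, replication-dependent histones (adjusted p = 0.0856) had HIST1H4C higher and HIST1H2BC lower, adjusted over the list alone. The histone list medians were -0.40 and -0.42 in the 3 day libraries and -0.67 and -0.50 at 7 days. These lay below both controls (-0.05 and 0.05), as did the 24 h libraries (-0.51 and -0.49). With the same trend removed, the histone median went from -0.44 to -0.65 at 3 days (random lists -0.40 to 0.35). At 7 days it went from -0.46 to -0.48 (-0.43 to 0.34).

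Ribosomal protein genes, p53 targets, oxidative phosphorylation genes and proteasome genes also rose as lists at 3 days, and their rise came with replicate 1. Ribosomal protein genes had a median of 0.97 with 55 of 55 higher (adjusted p = 1.1e-21), and p53 targets 0.60 with 34 of 39 higher (adjusted p = 0.00012). The medians were 0.40 for nuclear-encoded oxidative phosphorylation genes with 46 of 47 higher (adjusted p = 1.7e-07), and 0.27 for proteasome genes with 29 of 31 higher (adjusted p = 0.00269). Each of the 4 had adjusted p = 0.968 with an estimated correlation and 0 members adjusted over the list alone. Relative to the control mean, the median of p53 targets was 1.14 in replicate 1 and -0.26 in replicate 2, and that of ribosomal protein genes 1.49 and 0.16. In replicate 2 the medians of oxidative phosphorylation genes (0.07) and proteasome genes (-0.10) lay inside the control libraries. With the trend on gene length and GC content removed, the proteasome median went from 0.22 to 0.07, inside matched random lists (-0.15 to 0.10), and the oxidative phosphorylation median from 0.36 to 0.11 (random lists -0.13 to 0.09). The same step took the medians of ribosomal protein genes from 0.80 to 0.52 and p53 targets from 0.56 to 0.39. It took hypoxia and glycolysis genes from 0.63 to 0.42, DNA replication genes from 0.49 to 0.35 and mitosis genes from 0.34 to 0.25. All of these stayed above their random lists. Starting medians here and at 7 days are differences of mean log2 CPM, so they differ from the edgeR medians (0.97 for ribosomal protein genes). Replicate 1 at 3 days and at 7 days also had the lowest shares of reads counted under no feature, 39.4% and 36.5% against 44.4% to 51.5% in the other libraries. They had the highest shares of ambiguous reads, 1.05% and 1.12% against 0.608% to 0.781%. Without replicate 1 at 3 days the 4 calls were lost, with adjusted p = 0.0648 for ribosomal protein, 0.268 for p53, 0.259 for oxidative phosphorylation and 0.347 for proteasome genes, and the p53 and proteasome directions turned. The proteasome call was also lost without control replicate 2 (adjusted p = 0.106). The cell cycle inhibitor CDKN1A, named after its values were seen, stood at 387 CPM in replicate 1 and 73.9 in replicate 2, against 103 and 79.2 in control.

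**Figure D2:**
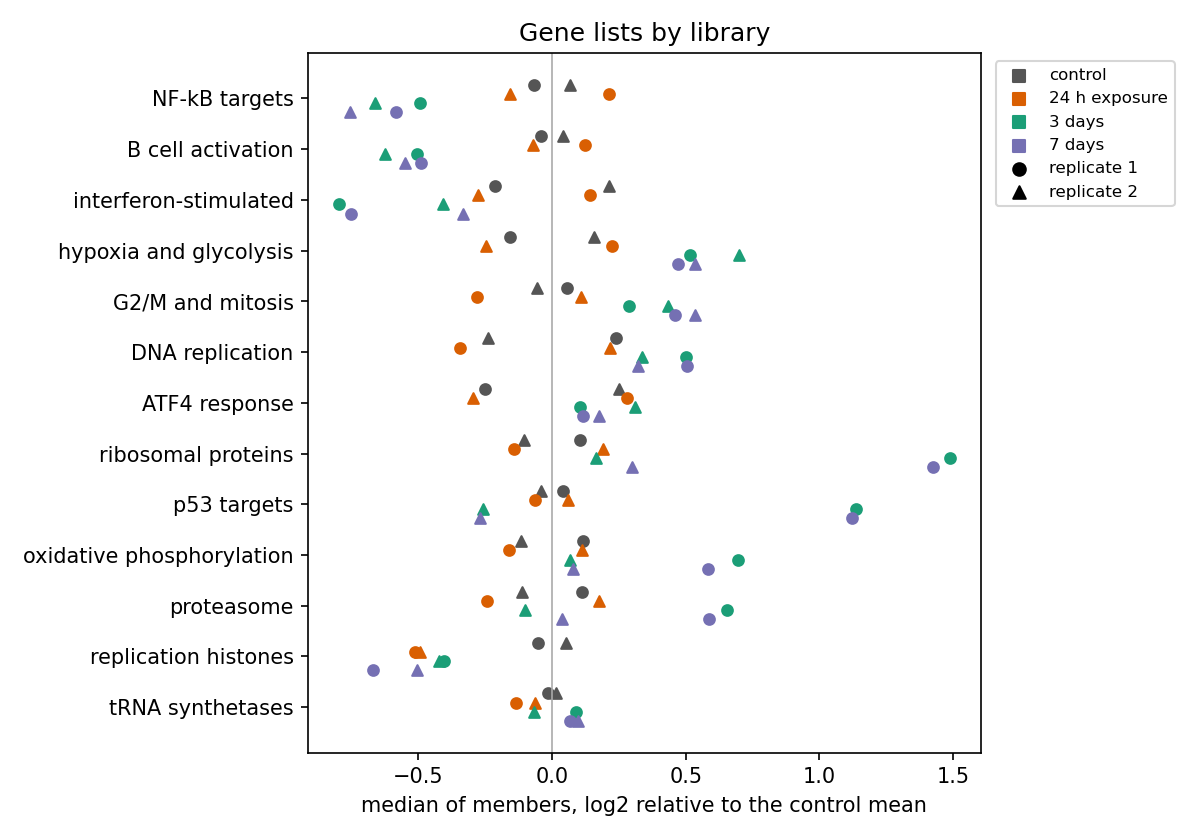
Median over the members of each of 13 gene lists (y axis) in each library, as log2 difference from the control mean (x axis); colour gives the group and shape the replicate number. NF-kB targets are at -0.49 and -0.66 at 3 days and at -0.58 and -0.76 at 7 days, whereas p53 targets are at 1.14 and 1.12 in replicate 1 and at -0.26 and -0.27 in replicate 2.

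At 7 days post treatment, compared with control, the 11 lists called at 3 days were also called, in the same direction. This is not an independent repeat, since both comparisons share the control libraries, and 3 and 7 day libraries of the same number resembled each other (correlation of replicate differences 0.81). NF-kB targets fell with 26 of 27 members lower, a median of -0.72, and 10 members lower adjusted over the list alone (adjusted p = 1.5e-16; adjusted p = 0.377 with an estimated correlation). B cell activation genes fell with 18 of 22 lower and a median of -0.34 (adjusted p = 8.9e-07; adjusted p = 0.354 with an estimated correlation), with 4 lower adjusted over the list alone. Interferon-stimulated genes fell with 27 of 30 lower and a median of -0.62 (adjusted p = 2.4e-08; adjusted p = 0.805 with an estimated correlation; 0 adjusted over the list alone). The interferon median was -0.75 in replicate 1 and -0.33 in replicate 2, against -0.21 and 0.21 in the control libraries. NFKB2 stood at 75.4 ± 0.78 CPM and TRAF1 at 94.3 ± 8.90. CD80 stood at 114 ± 11.3 and GBP1 at 96.3 ± 9.47.

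Mitosis genes rose at 7 days with 29 of 32 higher and a median of 0.49 (adjusted p = 4.3e-12; adjusted p = 0.637 with an estimated correlation). Hypoxia and glycolysis genes rose with 31 of 32 higher and a median of 0.60 (adjusted p = 6.7e-10; adjusted p = 0.697 with an estimated correlation), as did DNA replication genes with 32 of 36 higher and a median of 0.40 (adjusted p = 1.8e-07; adjusted p = 0.968 with an estimated correlation). The DNA replication medians were 0.51 and 0.32 in the 7 day replicates, against 0.24 and -0.24 in the control libraries. The proliferation marker MKI67 stood at 627 ± 46.5 CPM against 416 ± 8.51 in control, and the histone demethylase gene KDM3A at 392 ± 13.5 against 247 ± 29.7. Ribosomal protein genes rose with a median of 0.97 and 55 of 55 higher (adjusted p = 8.4e-23), p53 targets with 0.57 and 33 of 39 (adjusted p = 0.00026), and oxidative phosphorylation genes with 0.38 and 44 of 47 (adjusted p = 1.7e-06). Proteasome genes rose with 0.31 and 31 of 31 (adjusted p = 0.00015), and ATF4 response genes with 0.13 and 19 of 29 (adjusted p = 0.0496). Both 7 day medians of the ATF4 list (0.12 and 0.17) lay inside the control libraries (-0.25 and 0.25), as did replicate 2 for oxidative phosphorylation (0.08) and proteasome genes (0.04). With the trend on gene length and GC content removed, the medians went from 0.15 to 0.04 for ATF4 (matched random lists -0.18 to 0.11), from 0.34 to 0.07 for oxidative phosphorylation (-0.15 to 0.08) and from 0.28 to 0.09 for proteasome genes (-0.16 to 0.08). They went from 0.87 to 0.51 for ribosomal protein genes, from 0.46 to 0.28 for p53 targets, from 0.61 to 0.38 for hypoxia and glycolysis, from 0.42 to 0.26 for DNA replication and from 0.50 to 0.33 for mitosis, all above their random lists. The ribosomal protein, p53, oxidative phosphorylation, proteasome and ATF4 lists each had adjusted p = 0.968 with an estimated correlation, and 0 members of the lists that rose passed adjusted over the list alone. Without replicate 1 at 7 days, p53 targets were called lower (adjusted p = 0.0192), the oxidative phosphorylation (0.371), proteasome (0.678) and ATF4 (0.105) calls were lost, and ribosomal protein genes were still called (3.8e-05). The ATF4 call was also lost without control replicate 1, 3 day replicate 1 or 7 day replicate 2 (highest adjusted p 0.837). The other 21 lists did not pass at 7 days (adjusted p from 0.0709 to 0.934).

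ITGA1 stood at 22.8 ± 0.77 CPM at 7 days (log2 fold change against control -1.70 ± 0.21 SE, adjusted p = 0.481) and CCL22 at 230 ± 38.4 (-1.45 ± 0.26). VCAM1 stood at 2.00 ± 0.13 and, unlike at 3 days, was not called by DESeq2 on all genes. CREB3L1, an endoplasmic reticulum transcription factor, stood at 0.16 ± 0.09 against 3.48 ± 0.44 (-4.35 ± 0.64). CYP1B1, a cytochrome P450 induced by aryl hydrocarbons, stood at 4.85 ± 1.89 against 17.7 ± 3.77 (-1.87 ± 0.38), and ALPK2 at 5.81 ± 0.68 against 17.0 ± 3.11 (-1.55 ± 0.27). KIF26B (-2.24 ± 0.47) and ABCA9 (-1.94 ± 0.41) were also among the smallest p values. Both 7 day libraries lay on the same side of both control libraries for 34.5% of genes, where chance gives 33.3%. edgeR called 0 genes. Against 627 expected by chance, 619 had an unadjusted p under 0.05 (232 higher and 387 lower). That number was 374 without control replicate 1, 191 without control replicate 2, 289 without 7 day replicate 1 and 1734 without 7 day replicate 2. limma-voom called 0, and DESeq2 called 0 higher and 15 lower on all genes and 0 higher and 18 lower on the genes that edgeR used. Control cells were sampled before exposure, and unexposed cells at 3 or 7 days were not analysed here, so these differences are between times as well as between exposures.

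**Figure D3:**
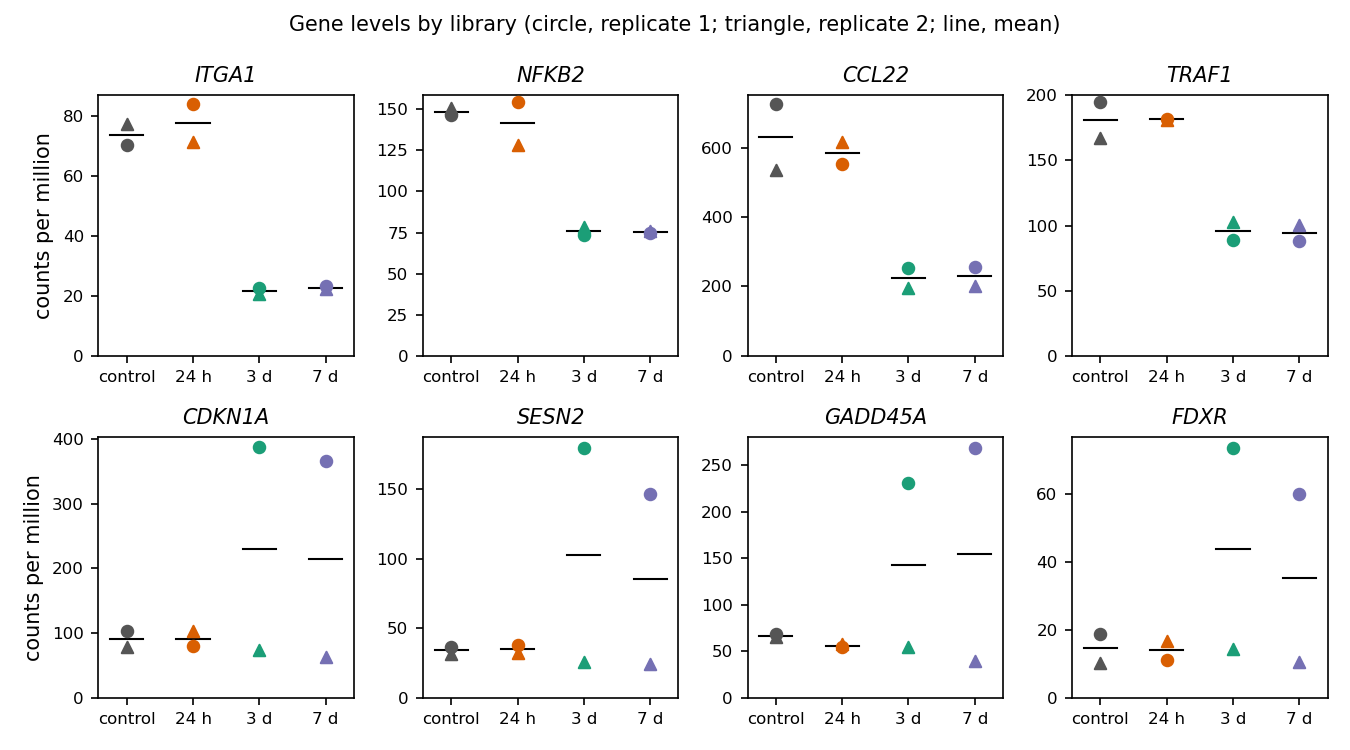
TMM-scaled CPM (y axis) of 8 genes by group (x axis); circles are replicate 1, triangles replicate 2 and lines the mean of 2 libraries. ITGA1 and NFKB2 are lower in both replicates at 3 and 7 days, whereas CDKN1A stands at 387 and 366 in replicate 1 and at 73.9 and 63.6 in replicate 2; CDKN1A, SESN2, GADD45A and FDXR were chosen after their values were seen.

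The comparisons between exposed groups ask what differed after the end of exposure from its 24 h point. ITGA1 stood at 77.7 ± 8.78 CPM at 24 h, a log2 fold change of -1.84 ± 0.21 SE at 3 days (adjusted p = 0.269) and -1.77 ± 0.21 at 7 days (adjusted p = 0.357). VCAM1 was at 6.42 ± 1.83 at 24 h and 0.95 ± 0.18 at 3 days (-2.74 ± 0.42), and TNFAIP2, a gene induced by tumour necrosis factor, at 37.0 ± 6.95 at 24 h and 14.3 ± 0.36 at 7 days (-1.37 ± 0.25). edgeR called 0 genes in each of the 3 comparisons. Unadjusted p was under 0.05 for 764 genes at 3 days against 24 h, 747 at 7 days against 24 h and 31 at 7 days against 3 days, with 627 expected by chance in each. Between 7 and 3 days 11.6% of genes were separated by group, where chance gives 33.3%. Libraries of the same number at these times resembled each other (correlation of replicate differences 0.81), and the unpaired fit counts the gap between replicates as noise. Its 0 calls therefore do not show that these times were alike. The 764 became 266 without 24 h replicate 1, 339 without 3 day replicate 1 and 2269 without 3 day replicate 2. The 747 became 234, 335 and 1971 without 24 h replicate 1, 7 day replicate 1 and 7 day replicate 2. The 31 became 17 and 15 without control replicate 1 and 2, 146 and 114 without the 3 day replicates, and 90 and 181 without the 7 day replicates. On all genes DESeq2 called 1 higher and 18 lower, 3 higher and 19 lower, and 0, and limma-voom called 0 in each. Between 7 and 3 days the smallest p values included PSEN2, a presenilin gene, at 9.38 ± 1.09 against 5.16 ± 0.90 (0.86 ± 0.28), and VCAM1 at 2.00 ± 0.13 against 0.95 ± 0.18 (1.07 ± 0.43).

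Over all times together edgeR called 0 genes, with 446 at an unadjusted p under 0.05 against 627 expected by chance; limma-voom called 0, and DESeq2 65 on all genes and 68 on the genes that edgeR used. Because no gene was called at 24 h by edgeR or DESeq2, the counts of 24 h genes still changed at 3 days, still changed at 7 days, or moved back by 7 days were each 0. Across genes, which are not independent replicates, log2 fold changes at 3 and 7 days correlated with r = 0.86, where unchanged groups simulated against the same controls gave 0.25, and their covariance was 0.213 against 0.0513. Fold changes at 24 h correlated with those at 3 days with r = 0.15 (simulated 0.33) and at 7 days with r = 0.12 (simulated 0.34), with covariances of 0.0193 and 0.0158 against 0.0504 and 0.0507. The direction of both rested on single libraries: r was -0.06 and -0.10 without 24 h replicate 2, and 0.52 and 0.49 without control replicate 1. The r at 3 and 7 days was 0.50 without 3 day replicate 1 and 0.52 without 7 day replicate 1. With the spread pooled over groups the simulated correlations were 0.50. These simulations draw each library independently, whereas 3 and 7 day libraries of the same number resembled each other (correlation of replicate differences 0.81). Control and 24 h libraries of different numbers did so too (-0.60). The simulated values are therefore no baseline for 3 and 7 days, nor for 24 h with either later time. With single libraries, none in common between the 2 fold changes, r at 3 and 7 days was 0.38 to 0.75 for the same replicate number and -0.09 to 0.24 for different numbers.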

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

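The list tests between exposed groups were not among those fixed before the data were examined, and of the tests below those of other cell types, of exposure acting alike on both cultures and of replicate 1 alone were chosen only after the result was seen.

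Gene lists stood out because their change from control differed between times, by a camera test of the difference itself (adjusted p from 1.2e-18 to 0.0453). Compared with 24 h, the median log2 difference at 3 days was -0.76 for NF-kB targets, -0.59 for interferon-stimulated genes, -0.48 for B cell activation, 0.93 for ribosomal proteins, 0.57 for p53 targets, 0.56 for hypoxia and glycolysis, 0.47 for DNA replication, 0.41 for mitosis, 0.40 for the proteasome, 0.40 for oxidative phosphorylation, 0.23 for ribosome biogenesis and 0.042 for the ATF4 response. At 7 days against 24 h it was -0.74 for NF-kB targets, -0.56 for interferon-stimulated genes, -0.47 for B cell activation, 0.94 for ribosomal proteins, 0.52 for p53 targets, 0.50 for mitosis, 0.46 for hypoxia and glycolysis, 0.44 for DNA replication, 0.43 for the proteasome, 0.39 for oxidative phosphorylation, 0.27 for ribosome biogenesis and 0.22 for tRNA synthetases. Between 7 and 3 days it was 0.13 for heat shock genes and 0.10 for mitosis. Relative to control, ribosome biogenesis was at 0.33 in replicate 1 at both late times and at -0.09 and -0.06 in replicate 2, between the 24 h libraries (-0.30 and 0.13), and heat shock genes were at 0.41 and 0.50 in replicate 1 and at -0.03 in replicate 2. With an estimated correlation 0 of these calls held, with adjusted p from 0.50 to 0.986. At 3 days, replicate 2 lay between the 24 h libraries for the proteasome (-0.10, 24 h -0.24 and 0.18). It did so too for oxidative phosphorylation (0.07, 24 h -0.16 and 0.11) and ribosomal proteins (0.16, 24 h -0.14 and 0.19). So did replicate 1 for ATF4 (0.10, 24 h 0.28 and -0.30). For NF-kB, interferon, B cell activation, hypoxia, mitosis and DNA replication, every late library lay beyond both 24 h libraries in the direction called.

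The p53 targets were higher in replicate 1 than in replicate 2 at both late times, with a median difference of 1.23 at 3 days and 1.35 at 7 days, and SESN2, GADD45A and FDXR followed CDKN1A in this; these genes were chosen after their values were seen. A trend with gene length and GC content was removed, which explained 16.8% and 13.4% of the variance of the replicate difference, and the smaller median afterwards was 1.24, above the random lists matched on expression (up to 0.23), which argues against that trend as the cause. Of 53 markers of T and NK, myeloid, stromal or epithelial and erythroid cells, 0 reached 10 CPM and were at least 2-fold higher in replicate 1 at both times, which argues against cells of these types but not against another state or population of B-lineage cells, since B cell identity (-0.39 and -0.45, replicate 2 at 0.24 and 0.11) and plasma cell genes (-0.45 and -0.45, replicate 2 at 0.18 and 0.21) differed too. Exposure acting alike on both cultures would raise the list in replicate 2 as well, whose higher median was -0.259, below both controls, and this is part of the pattern itself rather than separate evidence. A p53 response in a single culture may lie behind the pattern. So may such a B-lineage state or a difference in RNA or library preparation. The same 2 libraries had fewer reads counted under no feature (39.4% and 36.5%, others 44.4% to 51.5%) and more ambiguous reads (1.05% and 1.12%, others up to 0.781%). None of these explanations was tested.

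The NF-kB and B cell activation lists were lower at 3 and 7 days. After the length and GC trend was removed from the fold changes, the smallest list median in size was -0.55, below the random lists (lowest bound -0.18), which argues against that trend as the cause. Replicate 1 alone would leave replicate 2 at the level of control, but the replicate 2 medians were -0.66 and -0.76 for NF-kB (controls -0.07 and 0.07) and -0.62 and -0.55 for B cell activation (controls -0.04 and 0.04). Exposure, time in culture and any batch that separates the late from the early libraries cannot be told apart, since control cells were sampled only before exposure and the labels give no batch. The lower NF-kB level is therefore a hypothesis about chromium at most, and may reflect any of these.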

How the results depend on the processing

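DESeq2 on the genes that edgeR used, the crossed pairing, the fit without both late replicate 1 libraries and the correlations with no library in common were chosen after seeing the data. Counts of called genes were 0 by edgeR and stayed 0 in all comparisons with RLE or upper-quartile scaling, limma-voom, the stricter filter, the 2 groups alone, robust empirical Bayes, each library left out, and both late replicate 1 libraries left out. In the order 3 days against control, 7 days against control, 3 days against 24 h, 7 days against 24 h and any time, DESeq2 on all genes called 9, 15, 19, 22 and 65 genes, DESeq2 on the genes that edgeR used 13, 18, 19, 33 and 68, and edgeR without a filter on low counts called 11, 16, 21, 25 and 67; for 24 h against control and 7 days against 3 days each called 0. DESeq2 thus called genes with either set of genes; the cause was not tested further. With the replicate number as a block, edgeR called 0 genes in every comparison and 2, 11 and 11 lists, and changed no call count; the numbers did not pair the samples in all groups (correlation of replicate differences -0.60 between control and 24 h, -0.32 and -0.31 between 24 h and 3 or 7 days, 0.34 and 0.32 between control and 3 or 7 days, and 0.81 between 3 and 7 days). Crossing the numbers between control and 24 h gave 6, 5, 19, 10 and 15 genes in that order, and 0 in the other comparisons.

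The 2, 11 and 11 lists called at 24 h, 3 days and 7 days became 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry, 1 at 24 h with RLE scaling, and 2, 8 and 11 without both late replicate 1 libraries. In that last fit p53 targets were called lower at 7 days (adjusted p = 0.00015). Leaving out a library gave 1 to 15 lists at 24 h: 9 without control replicate 1, control replicate 2 or 24 h replicate 2, 15 without 24 h replicate 1, 3 without 3 day replicate 2, and 1 without 3 day replicate 1 or either 7 day library. At 3 days the range was 8 to 13 and at 7 days 10 to 13. Under RLE scaling the tRNA synthetase call at 24 h had an adjusted p of 0.0514 and the ATF4 call at 7 days 0.0522. When a library is left out, the other of its group is assumed to vary like the other groups.

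Leaving out a library moved the correlation of fold changes at 24 h and 3 days between -0.064 (without 24 h replicate 2) and 0.521 (without control replicate 1), at 24 h and 7 days between -0.099 and 0.492 (the same libraries), and at 3 and 7 days between 0.503 (without 3 day replicate 1) and 0.908. Without 7 day replicate 1 the last was 0.52. With the stricter filter on counts these 3 correlations were 0.058, 0.031 and 0.921, against 0.154, 0.125 and 0.862 in the main fit. The first was also 0.253 without control replicate 2, 0.308 without 24 h replicate 1, 0.295 without 3 day replicate 1 and 0.018 without 3 day replicate 2, and the second 0.239 and 0.303 without the former 2 of these, 0.217 without 7 day replicate 1 and 0.031 without 7 day replicate 2. With single libraries and no library in common, the mean r in that order was -0.166, -0.179 and 0.56 for the same replicate number, and -0.0025, -0.028 and 0.071 for different numbers; single libraries also add noise, which lowers r. Of 2941 values for named genes, 2830 kept their direction and side of the threshold. No gene passed in the main fit, so a kept side means only that the gene stayed uncalled, and no call could be lost. Another 110 values passed the threshold under DESeq2 (35 on all genes, 40 on the genes that edgeR used), without a filter (24) or with crossed pairing (11). FARSB at 24 h turned to 0.00893 without 24 h replicate 1, the highest of values from -0.54. In the simulated data few 2-fold changes were recovered (2% at 24 h), so changes of that size in single genes were mostly below what these 8 libraries show.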

Other observations

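The contrast of the later with the earlier groups and the tests of the library structure below were chosen only after the result was seen. When the 3 and 7 day groups together were compared with control and 24 h together, edgeR called 1 gene, ITGA1, lower with a log2 fold change of -1.77 ± 0.15 SE (adjusted p = 0.0263), with 1778 genes at an unadjusted p under 0.05. This contrast treats 8 libraries as independent although they form 4 close pairs, so its SE and p may be too small (lowest chi-square per degree of freedom of a pair 4.33, against 22.6 or more between replicates). CREB3L1 (-3.86 ± 0.43), RASSF4 (-1.30 ± 0.16), CCL22 (-1.42 ± 0.18) and VCAM1 (-2.19 ± 0.29) followed with an adjusted p of 0.101.

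B cell identity genes had medians of -0.39 and 0.24 relative to control in the 3 day replicates and -0.45 and 0.11 in the 7 day replicates, and plasma cell genes -0.45 and 0.18, then -0.45 and 0.21. MHC class II genes were at 0.25 and -0.56 at 3 days and at -0.02 and -0.44 at 7 days. None of these lists passed in the comparisons with control. DESeq2 called ADM, a hypoxia-induced peptide hormone gene, higher at 3 days than at 24 h (log2 fold change 3.24) and at 7 days than at 24 h (3.21), and FOSB (2.48) and CDCA7L (1.11) higher at 7 days than at 24 h.

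Each library was closest to a library of another group. If replicate numbers marked cultures carried through all groups, the replicate differences would correlate positively in each pair of groups, but the lowest correlation was -0.599, between control and 24 h, which argues against it but restates the closeness of their differently numbered libraries. A library deposited in duplicate would differ by sampling noise alone, with a chi-square per degree of freedom near 1, and the lowest of the 28 pairs was 4.33. Over 100 of the possible splits of the 8 libraries into 4 pairs, limma-voom called 0 genes for the real groups, so that all 100 necessarily gave at least as many and their number says nothing about chance. Of them 15 gave over 100 genes, all of which join replicate 1 at 3 days with replicate 1 at 7 days. The highest, with 8831, is the pairing of closest libraries itself, so it restates a structure of the samples that the groups do not describe and adds no separate evidence. Cultures split after an earlier step, a shared preparation or exchanged labels may each underlie it, and none of these was tested.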
